A study of Mus musculus with 10 samples.

How the data were processed

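RNA from a small piece of dissected cortex of 10 mice on a C57BL/6 background was sequenced, 5 wild type and 5 homozygous for an allele of Stip1 that lacks the TPR1 domain (dTPR1). Per the labels, total RNA was extracted with TRIzol, and single-end libraries were made with the SENSE Total RNA-Seq kit, a kind of kit that keeps the strand of the RNA. Per the submitters' processing notes, TopHat, HTSeq and DESeq2 were used with build GRCm38.p5, and no versions or strand settings are given in the sources used here. The deposited values are raw read counts by the authors, 1 whole number for each of 53090 Ensembl gene IDs and library, not normalised. No row stood for unassigned reads (0 rows that name no gene), so the share of reads that fell outside the genes is not analysed here. Symbols, strands and coordinates came from GENCODE mouse release M21 on build GRCm38, in which 52403 of the IDs were found and 687 were not.

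Library totals ran from 667751 to 927242 counts, which is shallow for a transcriptome, and counts of 3 corresponded to between 3.38 and 4.47 CPM (counts per library total scaled to a common size) in a library. Reads without molecular identifiers are not independent molecules, so counting errors understate the true error. The strand of the counts was checked after the data were examined: each ID was classed by whether its exons lay opposite an exon of a gene on the other strand, opposite an intron only, within 5 kb downstream of such a gene, or opposite nothing. Because 94.2% of counts lay at IDs that face an exon on the other strand, a gene's own ID mostly does not measure that gene here. Counts were therefore also summed per opposite-strand gene, meaning the gene that holds at least 90% of the exon bases opposite to an ID. This assigned 8188 IDs to 7388 genes and covered 88.0% of counts. The assignment was inferred from positions and from the counts, not from reads. All counts of an ID went to its opposite-strand gene, however few bases they shared, so reads outside the shared bases are included. For example, the counts at mt-Nd6 (13552 to 14070) went to mt-Nd5 (11742 to 13565), which overlaps it only at an end. Parts of a gene that face no counted ID are not covered.

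The genotype comparison fixed before the data were examined used the gene IDs as deposited: edgeR 4.0.16 in R 4.3.3, TMM factors, the filterByExpr filter on group, robust quasi-likelihood fits without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. It tested 3027 IDs. The same fit on opposite-strand genes, added after the data were examined, tested 2021. Fold changes are dTPR1 homozygous over wild type on the log2 scale with standard errors (SE), and CPM are given as mean ± SD over 5 libraries per group. Per-animal list means used log2 CPM with a prior count of 2.

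For the 39 gene lists fixed beforehand, camera of limma 3.58.1 was run with a preset inter-gene correlation of 0.01 on lists with 5 or more tested members. After the data were examined, lists were also matched to the opposite-strand genes, with 5 or more and with 3 or more tested members. A list of sex-linked genes was not tested. Camera with an estimated correlation, fry and an exact permutation test of the list mean per animal, two-sided over 252 arrangements, were run beside it. The smallest p that this test can give is 0.0079. IDs within 10 Mb of Stip1 were compared with all other tested IDs by Fisher's exact test, two-sided.

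The genes named were chosen by a rule fixed beforehand: Stip1 in every library, the 10 IDs with the smallest p because fewer than 10 passed the threshold, and in each list the 2 members with the smallest p, or 4 where camera called the list. For the lists this rule was applied to the opposite-strand genes, a change made after the data were examined. The most abundant members and the most abundant transcripts were named as well, after their values were seen. Some genes that these rules select are not reported here, and the fits and list tests include them. A second striatal list and a cortical list were written after a principal component had pointed to striatal genes. Rgs8 and Six3 were taken out of the second list, before any correlation was computed, because the name of Rgs8 and that of Six3os1, a neighbour of Six3, had been seen in that component; the correlation with Rgs8 kept in was computed too and is given beside it.

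Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, age or animal number in the model, and each library left out. Added after the data were examined were the opposite-strand genes, the striatal level in the model, wild-type animals 2 and 3 left out together, and mitochondrial IDs left out. The fit was tested on simulated counts with the real means, library sizes and dispersions. Among 3027 simulated IDs, 60 were changed 1.5-fold, 73 were changed 2-fold and 67 were changed 4-fold. The fit recovered 19.2% of those changed 2-fold and 64.2% of those changed 4-fold. Among 2021 simulated opposite-strand genes, with 69, 66 and 65 changed, it recovered 37.9% and 80.0%. Simulated genes were drawn independently of each other. With fewer changed genes the adjusted threshold is harder to pass, so these shares may be too high for the real data. No within-group pair of libraries agreed within sampling noise, with a chi-square per ID of 8.37 to 20.3 over 20 pairs.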

Results

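The cortex of 5 wild-type mice and of 5 mice homozygous for the dTPR1 allele was compared by RNA sequencing. Stip1 encodes STI1, the co-chaperone that brings HSP70 and HSP90 together, and the comparison asks which transcripts differ when it lacks its TPR1 domain. Wild-type animals were 442 to 663 days old (mean 589.6 ± 90.8, SD, n = 5) and dTPR1 homozygous animals 541 to 630 days (592.6 ± 33.5, n = 5). Total counts averaged 820858 ± 118749 in wild type and 775069 ± 96288 in dTPR1 homozygous libraries (SD, n = 5 each), with 6350 ± 386 and 6817 ± 436 gene IDs counted. Neither totals nor numbers of IDs differed beyond the spread between animals, with p = 0.49 and p = 0.12 in exact permutation tests, two-sided.

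Judged by the positions of the counted IDs, most counts lay on the strand opposite to the annotated genes. Among the mitochondrial protein genes, mt-Nd6 is the one encoded on the minus strand, and it held a mean of 177911 counts per library. The 12 genes on the plus strand, which include mt-Co1 and mt-Cytb, held 220.1 counts together. The 14 plus-strand mitochondrial tRNA genes had 0 counts and the 8 minus-strand ones 5362 in sum. IDs whose exons face an exon on the other strand made up 16.8% of all IDs and 94.2% of counts, and 94 of the 100 IDs with most counts were of this kind. Protein-coding IDs with such an exon had 101.9 times the mean count of those that face no feature (mean 92.4 against 0.907). Their medians were 1.8 and 0.0, so the ratio of means rests on abundant IDs, mt-Nd6 among them. Values are therefore also given per opposite-strand gene, for example Gsk3a from the counts at 9130221H12Rik or Syp, a synaptic vesicle protein, from those at Gm14703.

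**Figure D1:**
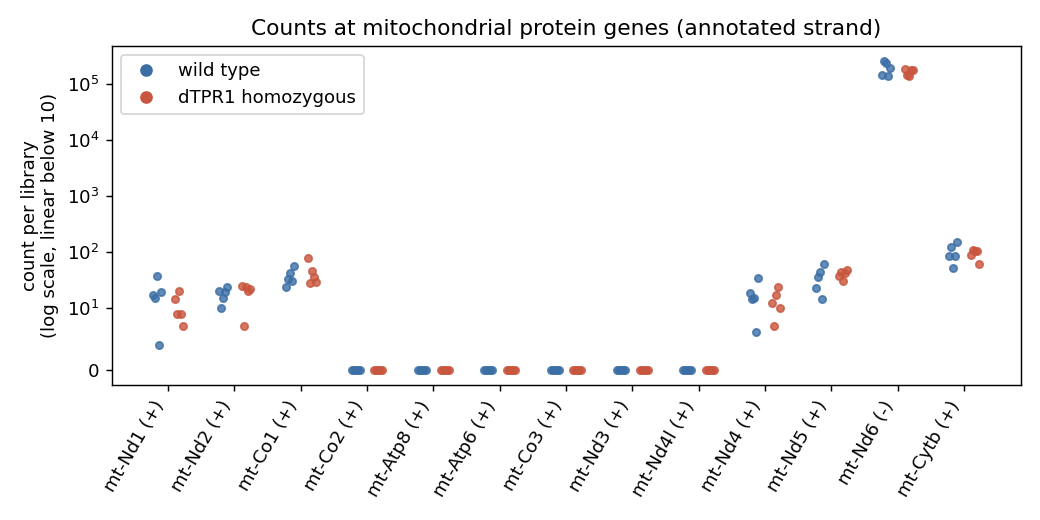
Counts per library (log scale, linear below 10) at the mitochondrial protein genes, with the annotated strand in brackets; points are libraries of wild-type and dTPR1 homozygous animals. The minus-strand gene mt-Nd6 held a mean of 177911 counts, and the 12 plus-strand genes 220.1 in sum.

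Stip1 itself (chromosome 19, 7020702 to 7039967, GRCm38) was counted 0, 4, 0, 8 and 0 times in wild-type animals 1 to 5 and 0, 8, 0, 5 and 0 times in dTPR1 homozygous animals 1 to 5. The mean was 3.32 ± 5.21 CPM in wild type and 3.48 ± 5.20 CPM in dTPR1 homozygous cortex (SD, n = 5 each; exact permutation p = 1, two-sided). Stip1 failed the filter on low counts, so the edgeR fit gave no value for it. No annotated exon of another gene lies opposite to it, so with counts on the other strand its transcript has no ID at which it would be counted. Neither the level of Stip1 nor the deletion could be checked at this depth and with these counts. Of 58 tested IDs within 10 Mb of Stip1, 0 had an unadjusted p under 0.05 in edgeR, against 77 of 2969 elsewhere (Fisher's exact test, two-sided, p = 0.40). At the adjusted threshold there were 0 on both sides.

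The 10 IDs with the smallest p did not pass correction. Bcas1os2 (ENSMUSG00000086999.1, chromosome 2, 170356361 to 170380435), opposite to Bcas1, a marker of myelin-forming oligodendrocytes, was counted at 755.3 ± 171.2 CPM in wild type and 1274 ± 295 CPM in dTPR1 homozygous cortex (log2 fold change 0.75 ± 0.19 SE, unadjusted p = 0.0010 and adjusted p = 0.997 in edgeR). Other IDs with higher means in dTPR1 homozygous libraries were Gm43579 opposite to the RNA helicase gene Ddx54 (0.85 ± 0.27), Gm17023 opposite to Pcid2 (1.08 ± 0.36), Gm15956 opposite to Npc1, which encodes a lysosomal cholesterol transporter (0.75 ± 0.25), Stab1 opposite to Nt5dc2 (0.82 ± 0.28) and Znrf1 opposite to Ldhd (0.52 ± 0.18). Lower means were found at Gm42521 opposite to Fam184b (-1.20 ± 0.34), Mdk, which lies downstream of the muscarinic receptor gene Chrm4 (-1.44 ± 0.45), Ryr1 opposite to Gm26604 and Gm44408 (-2.01 ± 0.65) and Gm20421 opposite to Hes5, a Notch target (-0.84 ± 0.28). In 9 of these 10, which were picked by their p, all 5 dTPR1 homozygous animals lay beyond the wild-type mean in the direction of the fold change (4 of 5 for Stab1), as they did in 14.3% of all tested IDs. Gm43579 was the one among them with every dTPR1 homozygous library above every wild-type library; such groups without overlap made up 0.363% of the tested IDs, where chance gives 0.794%. Gm42521, Mdk, Ryr1 and Gm20421 were highest in wild-type animals 2 and 3, which also had the highest striatal markers, and with the striatal level in the model their log2 fold changes were -0.42, -0.59, -0.57 and -0.71. Higher IDs moved as well, among them Gm43579 to 0.65 and Gm17023 to 0.89, which is as much as Gm20421 or more. Ryr1 stood at 67.1 ± 64.1 CPM in wild type and 16.7 ± 7.87 CPM in dTPR1 homozygous cortex, so the wild-type spread was nearly as large as its mean.

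Across all 3027 tested IDs, 0 passed an adjusted p of 0.05 in edgeR, and the smallest adjusted p was 0.997. At an unadjusted p under 0.05 there were 77 IDs, 36 higher and 41 lower in dTPR1 homozygous cortex, where 151.35 are expected by chance. Limma-voom on the filtered IDs also called 0, with 125 at an unadjusted p under 0.05. DESeq2 was run on all IDs without the filter on low counts and called 0 as well. Its 279 IDs at an unadjusted p under 0.05 are therefore not a share of the 3027. The opposite-strand genes gave 0 of 2021 and 57 at an unadjusted p under 0.05. Without the filter on low counts, edgeR called 2 IDs, Mdk and Gm42521, both lower (adjusted p = 0.043 each, and up to 0.9998 over the other settings). The biological coefficient of variation was 0.503, and the median SE of a log2 fold change was 0.47 over all tested IDs and 0.16 over the 130 IDs above 1000 CPM, so changes of the size of 2-fold were often not detectable.

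**Figure D2:**
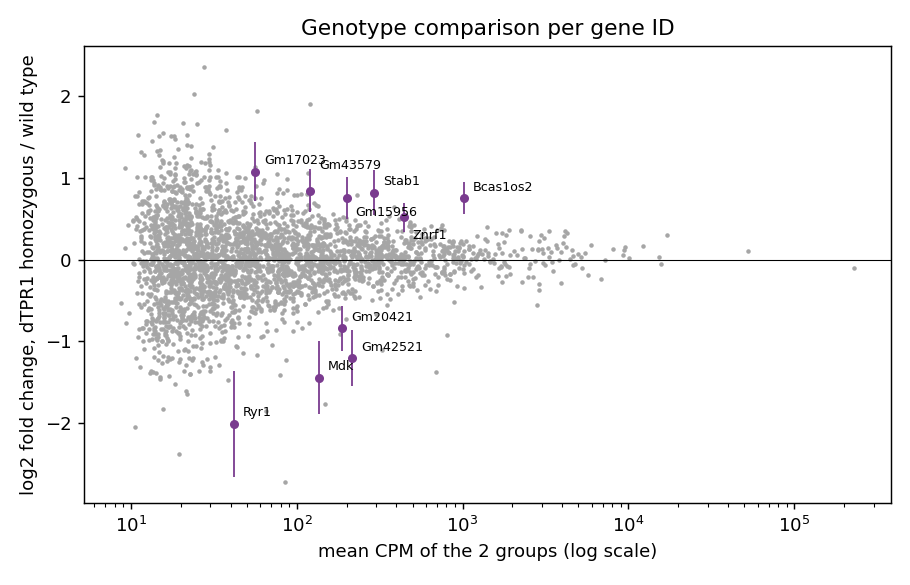
Log2 fold change of dTPR1 homozygous over wild type against mean CPM (log scale) for the 3027 tested IDs, 5 libraries per group; purple points are the 10 IDs with the smallest p, with bars of 1 SE. None passed the adjusted threshold in edgeR, and the spread of fold changes widens towards low counts.

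Genes of protein folding and turnover gave no call in edgeR. Among the 4 tested HSP70-HSP90 chaperones and co-chaperones, 2 had positive fold changes and 0 passed: Stub1, which encodes the ubiquitin ligase CHIP, was at 3080 ± 509 CPM in wild type and 3303 ± 196 CPM in dTPR1 homozygous cortex, and Dnajc7 had a log2 fold change of -0.30 ± 0.40. Hsp90b1, the HSP90 of the endoplasmic reticulum and the 1 tested member of the unfolded protein response list, was at 1185 ± 76 and 1151 ± 200 CPM. Of 4 chaperonin and prefoldin genes, Tcp1 was at 504.1 ± 91.4 and 585.4 ± 55.3 CPM and Pfdn2 had a log2 fold change of 0.23 ± 0.27. All 7 tested HSP90 client genes had positive fold changes, with Gsk3a at 17200 ± 3478 and 21019 ± 3643 CPM; the adjusted p of camera (edgeR fit) was 0.24 (adjusted p = 0.42 with an estimated correlation). Of 8 autophagy and lysosome genes, 5 had positive fold changes and 0 passed, Becn1 with -0.45 ± 0.21 and Lamp1 with 0.16 ± 0.13. The proteasome genes Psmb7 and Psmd3 had log2 fold changes of -0.16 ± 0.33 and 0.08 ± 0.39, with 0 of 3 members called.

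Stress, metabolic and neurodegeneration-linked genes showed no call either. Mt2, a metallothionein induced by glucocorticoids, was at 1872 ± 401 CPM in wild type and 2369 ± 521 CPM in dTPR1 homozygous cortex. Ddit3 and Cebpb of the integrated stress response had log2 fold changes of -0.67 ± 0.73 and 0.15 ± 0.94, the antioxidant gene G6pdx -0.30 ± 0.83, and Bcl2 and Gadd45a of the cell death list 0.88 ± 0.41 and 0.31 ± 0.43. All 5 tested nuclear genes of oxidative phosphorylation had negative fold changes, among them Uqcrc2 at -0.45 ± 0.30 and Ndufa9 at -1.09 ± 1.07 (-3.07 to -0.62 over the settings tried, -2.42 without dTPR1 homozygous animal 2), and the adjusted p of camera (edgeR fit) was 0.23 (adjusted p = 0.42 with an estimated correlation). Among 4 cytoplasmic ribosomal protein genes, 1 had a positive fold change, 0 with the other scalings, and Rpl5 was at -0.55 ± 0.56. The mitochondrial transcript counted at mt-Nd6, assigned to mt-Nd5, was at -0.12 ± 0.14, and mt-Co1, assigned from a tRNA gene of few counts, at -2.72 ± 1.28 (-1.13 without wild-type animal 5, -4.87 without dTPR1 homozygous animal 3). Of the neurodegeneration-linked genes, Bace1, the beta-secretase, had a log2 fold change of -0.29 ± 0.19, and Tardbp, which encodes TDP-43, was at 1431 ± 112 and 1485 ± 170 CPM.

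Synaptic and cell-type genes were likewise without a call over all genes tested. Of 11 presynaptic genes 6 had positive fold changes, 5 with the other scalings. Syp was at 10108 ± 1648 CPM in wild type and 11103 ± 1166 CPM in dTPR1 homozygous cortex, and Syn2 at a log2 fold change of 0.34 ± 0.25. Slc32a1, the transporter that loads GABA into vesicles, was at -0.55 ± 0.42 (-0.85 to 0.21 over the settings tried). Slc32a1 was highest in wild-type animals 3 and 2, at 2061 and 1740 CPM, which also had the highest striatal markers. The NMDA receptor subunit Grin1 was at 5088 ± 517 and 5209 ± 872 CPM, while Shank3 of the same 5-member postsynaptic list had a log2 fold change of 0.14 ± 0.25. Bcas1 was at 1320 ± 337 and 2026 ± 428 CPM, a log2 fold change of 0.62 ± 0.19, and above the wild-type mean in 5 of 5 dTPR1 homozygous animals. Adjusted over the list alone, it was the 1 call among the 2 tested oligodendrocyte precursor genes, the other being Gpr17 (0.25 ± 0.32). Its counts include those at Bcas1os2, named above for its small p, so this is not separate evidence. That adjustment did not correct across lists, and over all genes the adjusted p in edgeR was 0.999. No other list had a call adjusted over the list alone. Slc1a2 and Aldh1l1 of astrocytes had log2 fold changes of 1.07 ± 0.51 and 0.20 ± 0.31, Ctsb and Cd9 of disease-associated microglia -0.15 ± 0.21 and -0.25 ± 0.54, and Neurod1 of excitatory neurons 0.27 ± 0.45, Neurod1 being also the 1 tested hippocampal marker. Dlx1 of inhibitory neurons was at 0.53 ± 0.37 and Slc32a1, the other tested marker of these cells, at -0.55 ± 0.42, Slc2a1 of endothelium at 0.41 ± 0.37, Tagln of mural cells at -0.94 ± 0.66 (-1.19 to 0.11 over the settings tried, 0.018 without wild-type animal 2), Notch3 at -0.60 ± 0.66 (-1.34 to -0.20), Kcnj13 of choroid plexus at -1.46 ± 1.12 (-2.33 to -0.23), Rarres2 of ependyma at 1.11 ± 0.88 (-0.23 to 1.45), Lef1 and Rgs16 of thalamus at -0.42 ± 0.47 and 0.16 ± 0.60, and Tshz2 and Ccn2 of deep cortical layers at -0.11 ± 0.46 and -0.03 ± 0.57.

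Over the gene IDs as deposited, 7 lists had 5 or more tested members and 0 passed camera. Since a gene's own ID mostly does not measure that gene here, these 0 calls say little about the listed genes. Of the 39 lists, 12 had 3 or more members among the opposite-strand genes, 18 had 1 or 2, and 9 had none, among them heat shock targets, interferon response, mature oligodendrocytes and blood cells. In all, 83 of 802 list genes could be tested, so most of each list was not measured here. Changes with 1 library left out were examined in 49 opposite-strand genes. They are the 2 members with the smallest p and the most abundant member of each list, without Rarb and the genes not reported here. In 41 of the 49, leaving out 1 library moved the log2 fold change by more than 1.5 times or turned its sign. Those not among them were Bcas1, Bcl2, Becn1, Gsk3a, Penk, Ppp1r1b, Slc1a2 and Tcp1. Fold changes near 0, such as 0.03 for Grin1, meet this ratio easily, so the number does not measure dependence on single libraries alone.

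**Figure D3:**
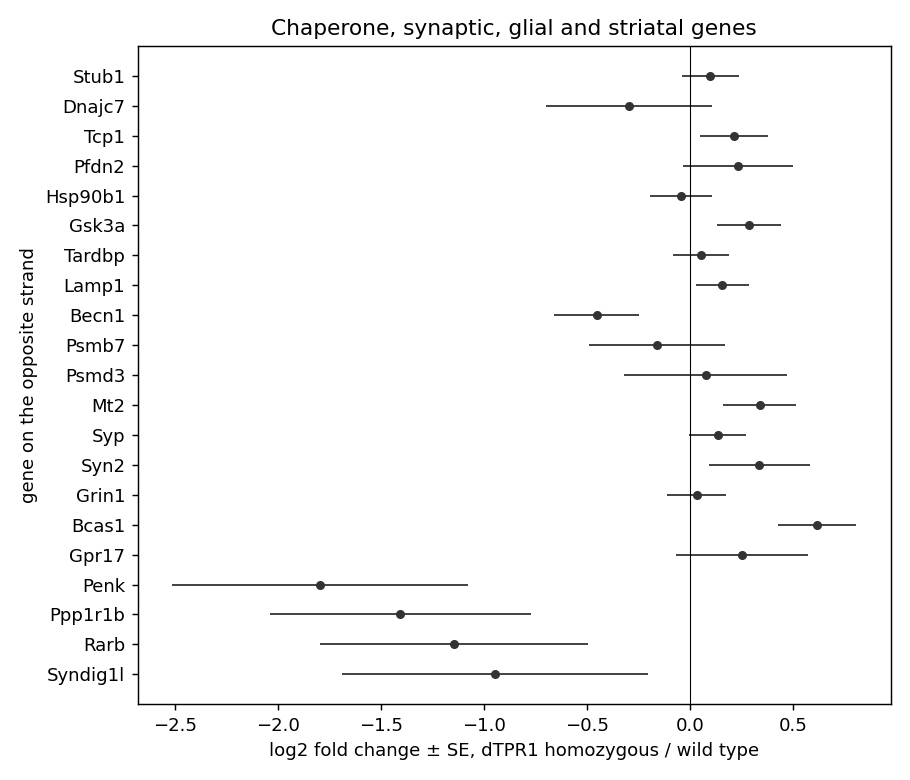
Log2 fold change with 1 SE, dTPR1 homozygous over wild type (5 libraries each), for some of the opposite-strand genes named from the lists. Among the genes drawn, Stub1, Syp and Grin1 lie near 0, and the 4 striatal genes lie lowest with the widest bars.

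Striatal markers were the 1 list that passed, among the 12 with 3 or more opposite-strand members, and it did not hold with an estimated correlation. Penk, which encodes enkephalin, was at 261.5 ± 209.1 CPM in wild type and 75.6 ± 41.6 CPM in dTPR1 homozygous cortex, and Ppp1r1b, which encodes DARPP-32 of medium spiny neurons, at 1137 ± 798 and 429.7 ± 244.2 CPM. Rarb was at 506.1 ± 435.4 and 229.4 ± 107.1 CPM and Syndig1l at 1193 ± 847 and 619.5 ± 562.3 CPM. The adjusted p of camera on the edgeR fit was 0.0024 with the preset correlation; it was 0.42 (adjusted p) with an estimated correlation, which came to 0.89 among the 4 genes. Their mean log2 CPM per animal was 8.93 ± 1.29 in wild type and 7.75 ± 0.99 in dTPR1 homozygous cortex (SD, n = 5 each; exact permutation p = 0.135, two-sided). Wild-type animals 3, 2 and 4 had the highest levels, 10.4, 9.85 and 9.20, and dTPR1 homozygous animal 4 the lowest, 6.25. Without wild-type animal 3 the adjusted p of camera was 0.085, and without wild-type animals 2 and 3 it was 0.78; over all settings tried it ran from 2.3e-05 to 0.94.

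**Figure D4:**
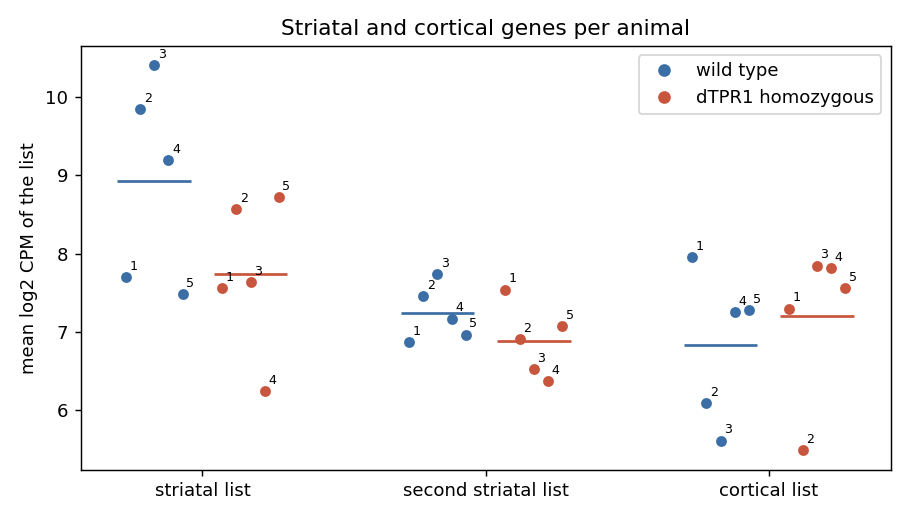
Mean log2 CPM per animal of the 4 striatal markers, of a second striatal list and of a cortical list; points are animals with their numbers and lines are group means. On the striatal list wild-type animals 3, 2 and 4 are highest, between 9.20 and 10.4.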

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

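The opposite-strand genes, whose values stand here, were chosen as a level after the data were examined. Groups of 5 values were examined for a single animal far from the others, and 15 of the 150 groups examined had one, where chance alone gives about 1 in 20, or 7.5, for normally spread values. CPM need not be spread in that way, and the groups share the same 10 libraries. Whether 15 is an excess was not tested. In wild-type animal 1, Slc2a1 was at 160.6 CPM and Tshz2, a deep-layer cortical gene, at 8718 CPM, both far above the other 4, and Rpl5 at 9.35 CPM was far below. Wild-type animal 2 had the highest values of Ccn2 at 1028 CPM and of Tagln, a smooth muscle gene, at 797.8 CPM. In wild-type animal 5 the choroid plexus gene Kcnj13 was at 206.1 CPM and the counts assigned to mt-Co1 at 587.8 CPM. Among the dTPR1 homozygous animals, animal 2 stood apart for Rarres2 at 290.6 CPM, Rgs16 at 212.8 CPM and Gnas at 80590 CPM, each the highest, and for B4galnt1 at 5559 CPM and the cortical list at a mean log2 CPM of 5.49, each the lowest, and animal 3 for Aldh1l1 at 222.1 CPM, mt-Co1 at 103.7 CPM and Tcp1, the lowest of its group at 487.0 CPM. No library total, number of counted IDs, mt-Nd6 share, mean count of the IDs seen in a single library or striatal level stood apart in this way.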

How the results depend on the processing

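The opposite-strand genes, the striatal level in the model, the models without wild-type animals 2 and 3 and the models without mitochondrial IDs were chosen after seeing the data. The 0 genes called by genotype held under each of these, under both other scalings, the stricter filter, DESeq2, limma-voom and age (0 to 0). An adjusted p under 0.1 and each library left out also gave 0. An added minimum of 1 in absolute log2 fold change must give 0 where 0 pass, so it tests nothing. Without a filter, edgeR called 2 gene IDs (Mdk and Gm42521) of 14428 and 2 opposite-strand genes (Fam184b and Prox1os) of 5181. The cause was not tested. Fam184b takes in the counts at Gm42521, so these 2 calls share their reads. Prox1os had 0 counts in every wild-type library and 0, 6, 7, 72 and 0 in dTPR1 homozygous animals 1 to 5, so its call rests mostly on animal 4. Numbers at an unadjusted p under 0.05 ran from 66 to 1300 over the settings on gene IDs, where 1300 came from no filter, and without wild-type animal 5 or dTPR1 homozygous animal 2 there were 130 and 121 instead of 77. On opposite-strand genes they ran from 45 to 543, with 103 and 89 without those animals instead of 57.

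Lists on gene IDs, which mostly do not measure the listed genes, and lists with 5 or more opposite-strand members gave 0 calls under each scaling, filter, covariate and left-out library tried for them. With 3 or more such members, 1 list, Striatum, was called with the other scalings, filters, limma-voom, age and without mitochondrial IDs, and with each library left out between 0 and 1. It was 0 without wild-type animal 3, without wild-type animals 2 and 3, with the striatal level in the model, with an estimated correlation, with fry and by permutation. With the striatal level in the model its median log2 fold change was 0.014 instead of -1.28, by construction, since that level is made of the same 4 genes. Adding animal number as a replicate block gave 0 genes and 0 lists on gene IDs, and 1 list on opposite-strand genes. The numbers do not pair the animals, since correlations of same-numbered animals ran from -0.09 to 0.12. The difference in Stip1 ran from -1.93 to 2.24 CPM over the libraries left out, within the spread between animals. Age, animal number and limma-voom gave no value for Stip1, which fails the filter. At an unadjusted p under 0.05, 0 IDs were called around Stip1 in windows of 5, 10 and 20 Mb. At the adjusted threshold 0 IDs were called anywhere, also with each library left out. Those calls around Stip1 must then be 0 as well. Of 49 named opposite-strand genes, 22 had a log2 fold change that turned sign in at least 1 setting and 0 under another scaling; Rarres2 ran from -0.23 to 1.45 and Rgs16 from -0.94 to 0.58. An Xist covariate was not run, since the condition set for it was not met. Depth and spread between animals limit all of this.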

Other observations

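The tests of strand, of clumped counts and of striatal and cortical lists were chosen after the results were seen; the other splits of the animals and the test of the lower gene IDs were set before theirs, though the striatal level used in the latter was itself chosen after the data were seen. The most abundant opposite-strand genes included neuronal and signalling genes, none of which passed the edgeR threshold. Gnas, the stimulatory G protein subunit, was at 57114 ± 3227 CPM in wild type and 60845 ± 11335 CPM in dTPR1 homozygous cortex, Chn1 at 13270 ± 3900 and 14814 ± 5632, and the long noncoding RNA Meg3 at 11226 ± 1348 and 11273 ± 1294 (SD, 5 libraries each). Brsk1, a kinase of neuronal polarity, was at 10259 ± 1221 and 10614 ± 2638 CPM and B4galnt1, which makes complex gangliosides, at 8690 ± 682 and 9385 ± 2145 CPM.

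Other splits of the 10 animals into 5 and 5 were fitted in the same way, 100 in number with the real one included. For gene IDs called in edgeR (real 0, highest other 5) and lists on gene IDs (real 0, highest other 1), all 100 splits gave as many, which they must where the real count is 0, so nothing follows from them. At an unadjusted p under 0.05, 74 splits gave as many IDs as the real 77, and chance cannot be excluded. The highest other split gave 275, several times as many, which points to a structure of the samples; what it is was not tested. For lists of 3 or more opposite-strand genes, 27 splits gave as many as the real 1 (highest other 3), and chance cannot be excluded.

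Reads counted on the strand opposite to each annotated gene are a candidate explanation for the near-zero counts at abundant genes, since 94.2% of counts lay at IDs that face an exon on the other strand. Low expression or degraded RNA is argued against by mt-Nd6, whose count was 808.3 times that of the 12 plus-strand mitochondrial protein genes together. The kit keeps the strand, so a counting setting for the other orientation could give this pattern. Apart from low expression, no biological explanation was tested.

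Counts also came in clumps. Of 4155 IDs counted in exactly 1 of the 10 libraries, 29.2% had a count of 1 there and 31.7% a count of 5 or more; these shares do not decide whether the counts are independent molecules, since differences between animals would lower the first share too. PCR copies of few starting molecules are a candidate cause: the mean count of these IDs was lower where more IDs were counted, with a Spearman rho of -0.95 (permutation p = 1.3e-04, adjusted 5.2e-04 over 4 relations) and Pearson's r of -0.89 (permutation p = 5.7e-04, adjusted 0.0023) over 10 libraries, and r of -0.87 without the 2 farthest, animal 3 of each genotype. Both measures come from the same counts of each library, so the relation does not single out PCR copies. The genotypes, at 4.46 ± 0.93 and 3.48 ± 0.58, cannot be told apart from chance in this measure (exact permutation p = 0.071, 5 animals each).

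The spread of striatal markers, which varied together within genotypes (lowest correlation 0.76), may come from unequal shares of striatal tissue in the dissected pieces. A second striatal list followed them with r of 0.760 (permutation p = 0.011, adjusted 0.022) and rho of 0.64 (permutation p = 0.054, adjusted 0.11) over 10 libraries. Of this list Gnal, Arpp21, Dlx6 and Foxo1 could be tested, and at least Arpp21 is also expressed in cortex. Without wild-type animal 3 and dTPR1 homozygous animal 4, r was 0.43. These animals had the highest and the lowest striatal level, and leaving out the ends of a range can itself lower r. Whether the relation rests on them is therefore not decided. With Rgs8 kept in the list, r was 0.64 and rho 0.43 (permutation p = 0.048 and 0.22, adjusted 0.048 and 0.22). A cortical list of 6 tested genes, some of them seen beforehand, went the other way (r of -0.71, permutation p = 0.021, adjusted 0.028; rho of -0.56, permutation p = 0.097, adjusted 0.13; r of -0.55 without those animals). With the striatal level in the model, 6 of the 41 lower and 14 of the 36 higher IDs at an unadjusted p under 0.05 stayed there (Fisher's exact p = 0.020), but the median log2 fold change shrank in both, from -0.87 to -0.67 and from 0.81 to 0.67. That test treats IDs measured in the same 10 animals as independent. The striatal level was also lower on average in dTPR1 homozygous libraries, so lower IDs could leave more often by construction. The p-value therefore does not decide the question. A lowering by the deletion cannot make wild-type animals differ, and these alone ran from 7.49 to 10.4 in mean log2 CPM, so it stays open only for the group difference (exact permutation p = 0.135), where it cannot be told apart from unequal shares with 5 animals each.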
